A study of Mus musculus with 16 samples.

How the data were processed

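The samples were pools of annulus fibrosus from the tails of C57BL/6 mice, labelled wild-type, at P5, P14, P21 and P28, with 4 pools per age. Per the labels' protocols, ribosomal RNA was depleted and the libraries were sequenced as read pairs of 150 bases. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to build GRCm38, counted per gene with featureCounts of Subread 1.5.2 and normalised with DESeq2. The notes do not give the strand setting of the counting. The deposited signal values are read counts that the authors divided by a size factor for each library, without a log. Multiplying each library by a single factor gave whole numbers within 0.001 reads for 100% of the values of every library. These factors ranged from 0.51 to 1.48 and were 0.9994 to 1.0006 times the size factors that DESeq2 gave on the recovered reads. The lowest mean of a gene was 8.0 and the lowest total 161 reads, so genes with few reads had been removed before deposition, by a rule that the notes do not state. Totals below are therefore those of the genes in the table.

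The table had 17724 genes. Symbols, positions and types came from GENCODE release 21 for mouse, which held 17677 of the identifiers, 14047 of them protein coding, and lacked 47. Genes with a mean of at least 10 over all libraries were tested, which left 17577 and removed 147. Values were log2 transformed after adding 1, and limma 3.58.1 was fitted in R 4.3.3 to all 16 libraries with a mean for each age and a trend in the prior variance (prior degrees of freedom 4.16, residual 12). The comparisons were P14 against P5, P21 against P14, P28 against P21, P28 against P5, and limma's F test over the 4 ages, all two-sided. The Benjamini-Hochberg adjusted p threshold was 0.05 in each. Comparisons that share an age are not independent of each other.

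For gene groups, 39 lists were fixed before the data were examined. They cover matrix, skeletal, cell cycle, growth, signalling, metabolic, clock, stress and cell type genes, and each had at least 5 genes tested. Lists were tested with camera at a preset correlation between genes of 0.01 and again with the correlation estimated from the data, with adjusted p over the 39 lists. Member genes were counted after adjustment over all genes and after adjustment over the list alone. The named genes were also set by a rule. In each comparison they are the 10 with the largest increase and the 10 with the largest decrease among those past the threshold, with a mean of at least 100 in the higher age and every library of one age beyond every library of the other. Predicted genes, clone names, pseudogenes and some classes of small RNA were left out. From each list up to 4 called members with the largest change were eligible, or the 2 with the highest mean if none was called. A further 16 genes of annulus matrix, tendon, proliferation, growth and signalling were followed in every comparison whatever their result. The comparisons, lists, rule and most alternatives were chosen before the data were examined.

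The alternatives were other pseudocounts and filters, rescaling to the same total or upper quartile, quantile normalization, robust limma, a replicate block, the 8 libraries of the pair of ages alone, leaving out each library, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and list tests without genes of more than 1 list. Chosen after the data were seen were a log2 Gm26917 covariate, the libraries with a Gm26917 share under or over 6%, leaving out 3 libraries with nervous system transcripts, averaging P21 replicates 3 and 4, leaving out 3 pools of mostly 1 sex, and the lists of mast cell, cornified-type, imprinted, central nervous system, peripheral nerve, marrow, osteoclast-restricted and annulus marker genes. DESeq2 gave no adjusted p for 3 genes in each comparison. Replicate libraries were compared in pairs by correlation and by chi-square per gene. P21 replicates 3 and 4, the closest pair, were kept as separate samples.

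The test was tested on simulated data with the libraries' own spread. It called 79.2% to 84.5% of genes changed 4-fold and 39.0% to 49.5% of genes changed 2-fold, with 5 to 9 false calls per comparison. A list shifted by 1 on the log2 scale was called in each comparison, and 0 of the 38 other lists were. The simulated genes were drawn independently, so false gene or list calls from correlated genes or library-wide differences could not appear. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. No library was left out of the values reported as the result of a comparison.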

Results

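RNA was sequenced from the annulus fibrosus, the fibrous outer ring of the intervertebral disc, of mouse tails at postnatal days 5, 14, 21 and 28 (P5, P14, P21 and P28). Each age had 4 libraries, 16 in all. Per the labels, each library came from a pool of 2 to 3 C57BL/6 mice of both sexes, with 10 discs from each mouse. Of the 17724 genes in the table, 17577 with a mean of at least 10 were tested. Reads in the table ranged from 11153528 to 20179991 per library at P5, from 10549937 to 23719004 at P14, from 17380812 to 22084986 at P21 and from 20263292 to 24782845 at P28. Errors of means are SD over the 4 libraries of an age, and errors of log2 fold changes are standard errors from limma, with n = 4 libraries per age unless another number is given. Positions are on build GRCm38.

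Col1a1 and Col2a1, the genes of the main collagens of fibrous tissue and cartilage, were among the most abundant transcripts and took 3.89% to 19.4% and 4.22% to 12.9% of the reads of a library. Gm26917 (ENSMUSG00000097971, chromosome 17, 39843013 to 39846341), a transcript with sequence shared with ribosomal RNA, took 8.49% to 12.1% of the reads in P5 replicates 1, 2 and 3 and 9.05% and 8.05% in P14 replicates 3 and 4. It took 1.71% to 5.12% in the other 11 libraries. The mitochondrially encoded genes together took 10.6% to 20.2% of the reads in those 5 libraries and 2.00% to 4.61% elsewhere. P5 replicate 4 was the P5 library with a low Gm26917 share, and each comparison below is therefore also given within the libraries under and over a share of 6%, a choice made after the shares were seen. Kdm5d, a gene of the Y chromosome, had 11.5 normalised reads in P14 replicate 4 against 206 to 703 in the other libraries. Xist, which is transcribed from the inactive X chromosome, had 528 in P14 replicate 3 and 141 in P28 replicate 4 against 3817 to 41590 in the others, so these 3 pools carried mostly the transcripts of 1 sex, which goes against the label of both sexes. Neuronal and glial transcripts were high in P14 replicate 2 and in P21 replicates 1 and 2. Snap25 (ENSMUSG00000027273, chromosome 2, 136713453 to 136782428), a synaptic vesicle fusion gene chosen after its values were seen, had 269.5, 840.1 and 747.5 there and 0 to 44.83 elsewhere. P21 replicates 3 and 4 resembled each other more than any other pair of one age did, with a correlation of 0.989 across genes, which are not independent replicates, against 0.92 to 0.974 in the other pairs. Their chi-square per gene was 2.66 against at least 28.61 in the other pairs. Whether they came from separate pools is not known, and they are counted as 2 of the 4 libraries of P21.

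**Figure D1:**
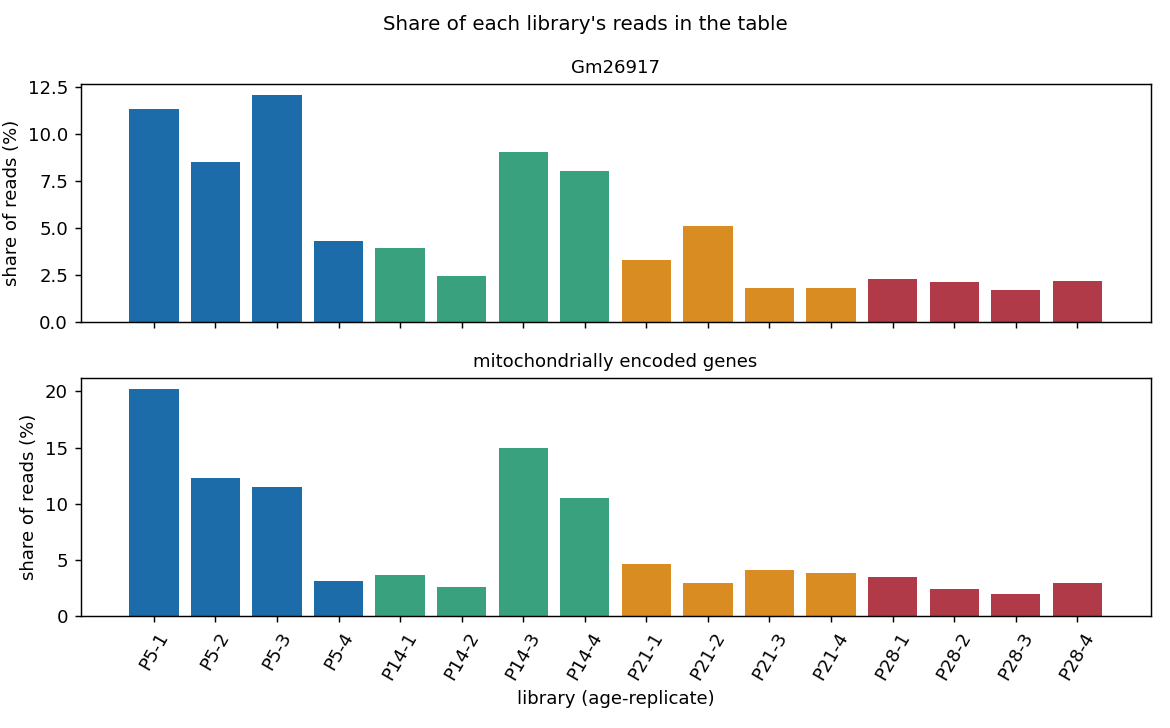
Bars give the percent of the reads of each library, 4 libraries at each of 4 ages, that fell on Gm26917 and on the mitochondrially encoded genes, on axes that start at 0. P5 replicates 1 to 3 and P14 replicates 3 and 4 have Gm26917 shares of 8.05% to 12.1%, and the other 11 libraries have 1.71% to 5.12%.

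The comparison of P28 with P5 asked how the tissue changed over the whole interval. Genes of the fetal and juvenile growth programme, a list of transcripts abundant in fast-growing young tissue, were lower at P28. Of its 22 genes, 21 fell, 0 rose and 1 was not called (camera adjusted p = 9.39e-18, and adjusted p = 0.0104 with an estimated correlation), and 21 fell when adjusted over the list alone. Dlk1 (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336), an imprinted gene for a Notch ligand-like protein, fell from 5086 ± 1203 to 17.98 ± 10.56 normalised reads, a log2 fold change of -8.23 ± 0.35 (adjusted p = 1.29e-09). Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), the insulin-like growth factor of fetal life, fell from 134300 ± 37400 to 8014 ± 2143 (-4.07 ± 0.33, adjusted p = 5.88e-07), and its neighbour H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), an imprinted noncoding RNA, from 104100 ± 16740 to 3285 ± 1906 (-5.18 ± 0.47). Mest, another imprinted gene, fell by 5.23 ± 0.42. Annotated genes share 64.5% of the exonic bases of Igf2 and 23.1% of those of Mest, and the strand setting of the counting is unknown.

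Tnr (ENSMUSG00000015829, chromosome 1, 159523769 to 159931729), which encodes the extracellular glycoprotein tenascin-R, rose from 10.61 ± 4.555 at P5 to 1436 ± 461.6 at P28, a log2 fold change of 6.99 ± 0.35 (adjusted p = 3.53e-09). Grem1 (ENSMUSG00000074934, chromosome 2, 113746164 to 113758646), a secreted antagonist of bone morphogenetic proteins, rose from 663.6 ± 373.1 to 57190 ± 13650 (6.60 ± 0.39). The other genes with the largest increases were Slurp1 (6.94 ± 0.50), S100a4 (5.88 ± 0.54), Fxyd3 (5.41 ± 0.47), Acp5 (5.26 ± 0.81), Sbsn (5.19 ± 0.25), Scel (5.17 ± 0.67), Dmkn (5.12 ± 0.42) and Lgi4 (4.82 ± 0.22). Fxyd3 and Lgi4 lie on opposite strands and share 2059 exonic bases, 42.5% and 44.9% of their exons, and 51.7% of the exonic bases of S100a4 lie in another annotated gene. After Dlk1, the largest decreases were in the embryonic and perinatal myosin genes Myh8 (-7.01 ± 1.497) and Myh3 (-6.87 ± 1.40), Col6a6 (-6.51 ± 0.52), Magel2 (-6.51 ± 0.98), the cartilage matrix gene Matn1 (-6.39 ± 0.86), the mast cell proteases Tpsb2 (-6.36 ± 0.67) and Cma1 (-5.74 ± 0.71), Lypd8 (-6.23 ± 1.11) and Egfl6 (-6.10 ± 0.71). In each of these genes all 4 libraries of one age lay beyond all 4 of the other, by the naming rule. Of the 30 called genes that were named by rank or chosen beforehand, 19 kept the call in the libraries under 6% Gm26917, where P5 is replicate 4 alone, and 17 kept it with the log2 Gm26917 share as a covariate. Myh8, Myh3, Lypd8, Col1a2, Acan, Scx, Tnmd, Mki67, Top2a, Tgfb1 and Gli1 lost it in both settings (adjusted p = 0.0655 to 0.91 and 0.13 to 0.948), and Acp5 and Magel2 with the covariate alone (0.0539 and 0.0908). The plot of 8 genes shows Tnr, Grem1, Dlk1, H19 and Igf2 by library.

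**Figure D2:**
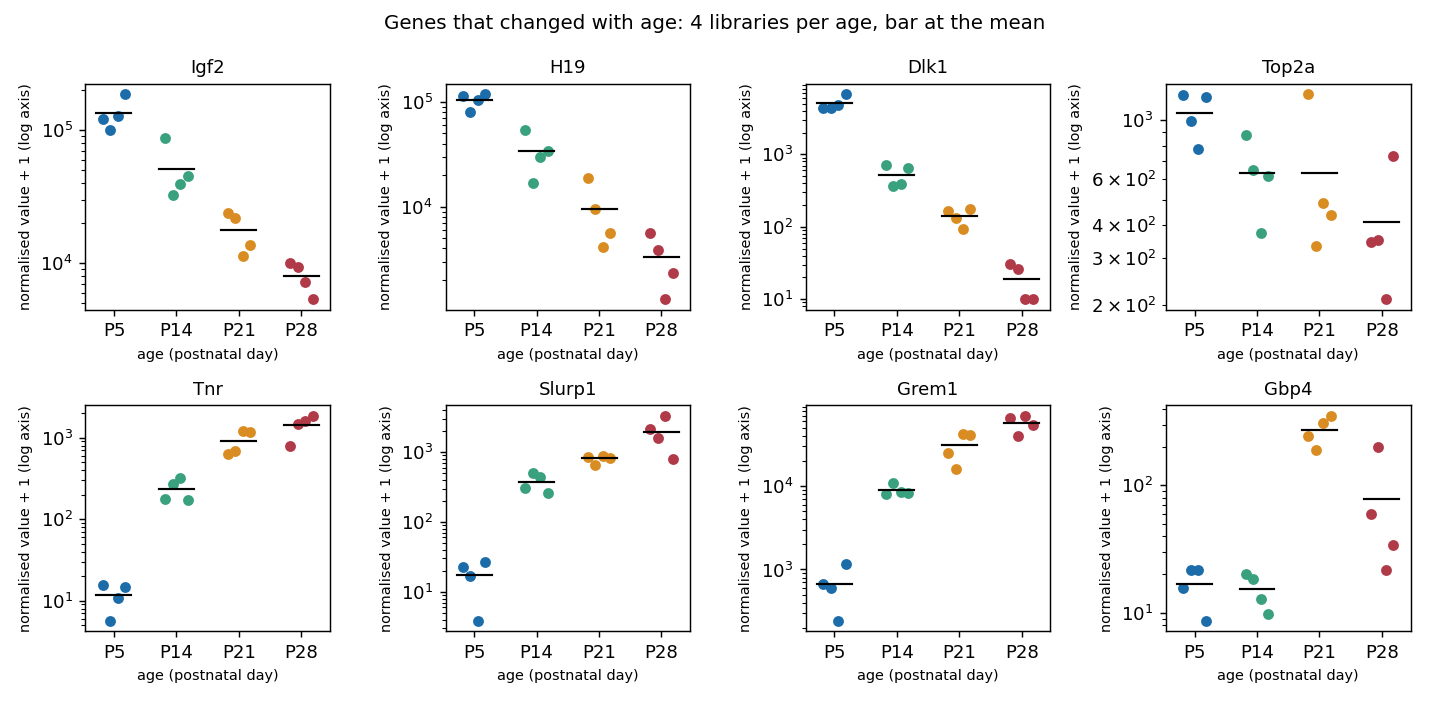
Normalised read counts + 1, on a log axis, of Igf2, H19, Dlk1, Top2a, Tnr, Slurp1, Grem1 and Gbp4 at P5, P14, P21 and P28, with 1 point per library (4 per age) and a bar at the mean of each age. The Dlk1 mean goes from 5086 at P5 to 17.98 at P28, and the Tnr mean from 10.61 to 1436.

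Among the genes used as markers of the annulus and tendon, Tnmd, a tendon membrane protein gene, rose from 1710 ± 465.3 at P5 to 5311 ± 3503 at P28 (1.45 ± 0.37, adjusted p = 0.00895). Col1a2 rose by 1.95 ± 0.53 (adjusted p = 0.0115), while Col1a1 differed by 1.63 ± 0.87 (adjusted p = 0.175) and was not called. Acan, the gene of the large cartilage proteoglycan aggrecan, rose by 1.22 ± 0.41 (adjusted p = 0.0354). Its call was lost without P5 or P28 replicate 1, 2 or 3 (adjusted p = 0.0555 to 0.12). The Acan sign turned to -0.13 under 6% Gm26917. Tgfb1, the gene of a growth factor that drives matrix synthesis, rose by 1.01 ± 0.17 (adjusted p = 0.00037). Gli1, a transcriptional target of Hedgehog signalling, fell by 0.85 ± 0.28 (adjusted p = 0.0345), a call lost without P5 replicate 1, 2 or 4 or P28 replicate 1 or 3 (adjusted p = 0.054 to 0.109). The differences of Col2a1 (0.48 ± 0.73), Eln (0.74 ± 0.30, adjusted p = 0.0717), Lox (0.93 ± 0.36, adjusted p = 0.0628), Mkx (0.29 ± 0.20) and Sox9 (0.77 ± 0.28, adjusted p = 0.0502) were not called.

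Scx (ENSMUSG00000034161, chromosome 15, 76457452 to 76459458, plus strand), a transcription factor gene of tendon and annulus cells, lies in an intron of Bop1 (ENSMUSG00000022557, chromosome 15, 76452989 to 76477277, minus strand), a ribosome biogenesis gene with which it shares 0 exonic bases. Scx rose from 2597 ± 3781 to 6181 ± 2579 normalised reads between P5 and P28 (2.13 ± 0.62, adjusted p = 0.0184). It had 662, 845 and 614 in P5 replicates 1, 2 and 3, 8267 in P5 replicate 4, and 2433 to 12876 in the libraries of the later ages. Bop1, which was chosen after its values were seen, had 663.3, 488 and 473.4 in P5 replicates 1, 2 and 3, 17620 in P5 replicate 4 and 4696 to 30820 later, and rose by 3.00 ± 0.86. Fabp2 (ENSMUSG00000023057, chromosome 3, 122895072 to 122899506), also chosen after its values were seen, had 0, 0 and 4.165 in P5 replicates 1, 2 and 3, 52.56 in P5 replicate 4 and 21.8 to 116.6 later. In the libraries under 6% Gm26917, where P5 is replicate 4 alone, the Scx difference was -0.54. The Scx call was lost without P5 replicate 1, 2 or 3 or P28 replicate 2 (adjusted p = 0.0529 to 0.0636). Neither edgeR (1.24, adjusted p = 0.188) nor DESeq2 (1.25, adjusted p = 0.165) called Scx. The flanking genes Mroh1 and Hsf1 ranged from 286.5 to 531.8 and from 237.1 to 490.1 over the 16 libraries, and of these Hsf1 fell by 0.56 ± 0.14 between P5 and P28.

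**Figure D3:**
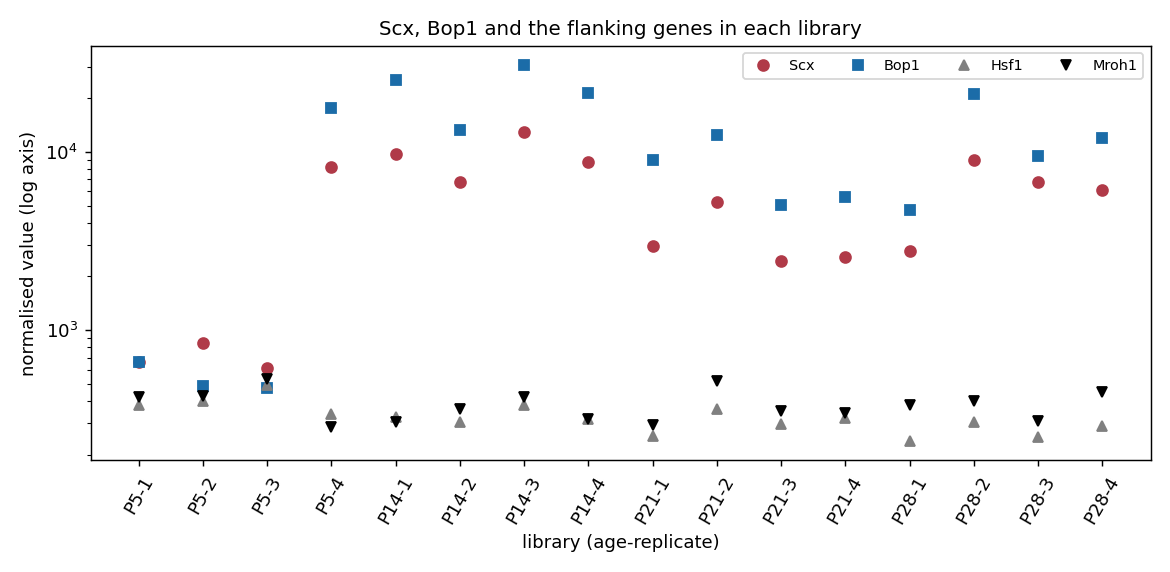
Normalised read counts, on a log axis, of Scx, Bop1 and their neighbours Hsf1 and Mroh1 in each of the 16 libraries, with 1 point per library, grouped by age. Scx and Bop1 are low together in P5 replicates 1 to 3 (614 to 845 and 473.4 to 663.3) and high together in P5 replicate 4 (8267 and 17620), while Mroh1 stays between 286.5 and 531.8.

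The matrix gene lists changed in both directions between P5 and P28. Of 11 fibril-associated and type VI collagens 3 rose, 6 fell and 2 were not called, also over the list alone. Col14a1, which regulates fibril diameter in young tendon, fell by 5.37 ± 0.31 and the cartilage collagen gene Col9a1 by 2.34 ± 0.44. Of 14 small leucine-rich proteoglycans 6 rose and 6 fell, also over the list alone. Chad, a gene of a cell-binding cartilage protein, rose by 3.21 ± 0.36, and Kera and Epyc fell, with values of -5.31 ± 0.59 and -4.49 ± 0.66. Of 17 elastic fibre genes 1 rose and 8 fell, or 2 and 9 adjusted over the list alone. Its microfibril genes Mfap4 and Fbn2 fell, with values of -3.52 ± 0.42 and -3.13 ± 0.21 (camera adjusted p = 0.00736 for the list, and adjusted p = 0.461 with an estimated correlation). Of 29 genes for collagen processing and crosslinking 13 rose and 3 fell, or 16 and 5 adjusted over the list alone. Pcolce2, a procollagen processing enhancer, rose by 3.68 ± 0.34 and P4ha3, a prolyl hydroxylase subunit, fell by 2.51 ± 0.22 (camera adjusted p = 0.0256, and adjusted p = 0.703 with an estimated correlation). The camera call of this list was lost without P5 replicate 1, P5 replicate 3 or P28 replicate 3 (adjusted p = 0.0783 to 0.0934). Its median of 0.58 turned to -0.04 with the log2 Gm26917 share as a covariate and to -0.15 in the libraries under 6%. The hypertrophy and mineralisation list had 7 of 14 genes that rose and 0 that fell, with the same counts adjusted over the list alone, among them the bone matrix genes Spp1 (4.50 ± 0.52) and Ibsp (4.06 ± 0.65). Its camera adjusted p was 0.00147, and the adjusted p was 0.461 with an estimated correlation. The osteoblast and osteocyte list (median 2.14) and the osteoclast list (median 3.45) were higher in the same comparison, each with an adjusted p of 0.461 with an estimated correlation.

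Camera called neither the fibril-associated and type VI collagens (adjusted p = 0.137) nor the small leucine-rich proteoglycans (adjusted p = 0.985), nor the fibrillar collagen, cartilage-type, protease, tendon-type and chondrogenic lists. Of 11 fibrillar collagens Col1a2 rose and Col5a3 fell, also over the list alone, while edgeR called 4 and DESeq2 5. The Col5a3 change (-1.15 ± 0.36, adjusted p = 0.0258) was lost without P5 replicate 1, 2 or 3 or P28 replicate 3 (adjusted p = 0.0666 to 0.091) and turned to 0.41 in the libraries under 6% Gm26917. Of 18 cartilage-type matrix genes 6 rose and 4 fell over all genes and over the list alone, with Cilp2 at 3.80 ± 0.31 and Matn4 at -3.99 ± 0.49. The matrix proteases and inhibitors had 8 genes up and 6 down of 20, and 8 in each direction adjusted over the list alone, with increases of Mmp9 (4.79 ± 0.85), Timp4 (4.75 ± 0.49) and Mmp3 (3.86 ± 0.37). Of 14 tendon-type genes 4 rose and 3 fell, also over the list alone. Of 13 chondrogenic and sclerotome regulators 4 rose and 2 fell, or 6 and 2 adjusted over the list alone, among them Nkx3-2 (1.06 ± 0.25) and Pax9 (0.83 ± 0.21). The median, the mean and the camera direction differed in sign for the small leucine-rich proteoglycans (median -0.29, mean -0.46, direction up), the cartilage-type matrix (0.23, -0.12, up) and the tendon-type genes (0.25, -0.28, up).

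Cell cycle genes were lower at P28 than at P5. In the G2/M phase list 21 of 27 genes fell and 0 rose, or 25 and 0 adjusted over the list alone, among them the spindle genes Nuf2 (-1.81 ± 0.40), Ttk (-1.78 ± 0.41) and Kif11 (-1.73 ± 0.38). The proliferation marker Mki67 fell by 1.44 ± 0.38 (adjusted p = 0.0102) and the topoisomerase gene Top2a by 1.49 ± 0.39 (adjusted p = 0.0101). In the S phase list 17 of 28 genes fell and 1 rose, or 20 and 1 adjusted over the list alone, with Dtl at -2.01 ± 0.30. Camera adjusted p was 6.62e-09 for G2/M and 5.38e-06 for S phase, and for both lists the adjusted p was 0.461 with an estimated correlation. The plot of list scores shows the 4 ages library by library.

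**Figure D4:**
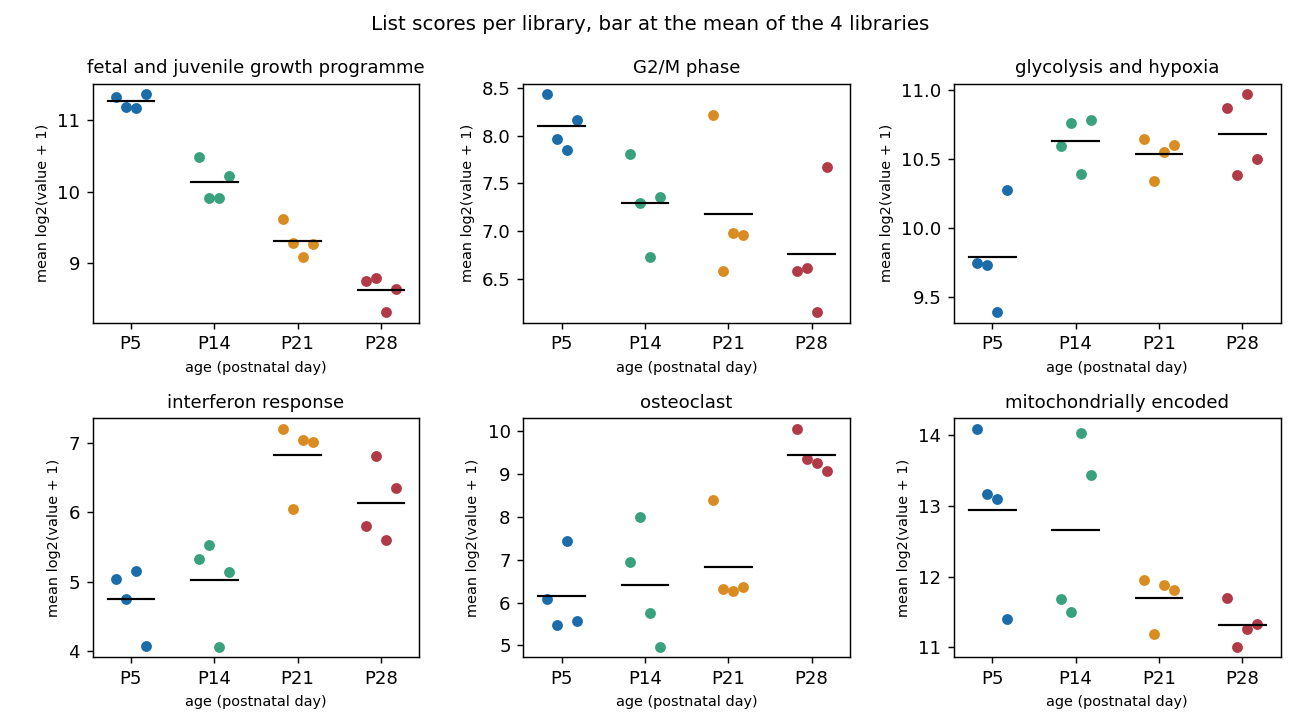
Score of 6 gene lists, the mean log2 of normalised read count + 1 over the genes of the list, for each library at P5, P14, P21 and P28, with 1 point per library (4 per age) and a bar at the mean of the age. The growth programme score lies between 11.18 and 11.36 at P5 and between 8.32 and 8.79 at P28.

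Metabolic, clock and stress lists were mostly higher at P28 than at P5. Of 26 glycolysis and hypoxia genes 16 rose and 0 fell, or 19 and 0 adjusted over the list alone, with Ndrg1 at 2.499 ± 0.23 and the oxygen sensor Egln3 at 1.89 ± 0.31 (camera adjusted p = 3.62e-07). Of 18 circadian clock genes 11 rose and 0 fell, or 11 and 2 adjusted over the list alone, with the clock output gene Dbp at 3.20 ± 0.29 and the repressor gene Nr1d1 at 3.08 ± 0.24 (camera adjusted p = 3.84e-05). Of 22 interferon response genes 12 rose and 0 fell, or 14 and 0 adjusted over the list alone, with Ifit3 at 3.23 ± 0.65 (camera adjusted p = 1.29e-05). The immediate-early and heat shock list had 7 of 20 genes that rose and 0 that fell, over all genes and over the list alone, with Dusp1 at 2.01 ± 0.34 (camera adjusted p = 0.00814). For these 4 lists the adjusted p was 0.461 with an estimated correlation. Of 27 secretory and chaperone genes of the endoplasmic reticulum 8 rose and 0 fell, with the same counts adjusted over the list alone, with Dnajb9 at 1.30 ± 0.23 (camera adjusted p = 0.00208, and adjusted p = 0.655 with an estimated correlation). Its median of 0.50 turned to -0.20 with the Gm26917 covariate and to -0.12 in the libraries under 6%. Of 35 nuclear genes of oxidative phosphorylation 2 rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.798 with an estimated correlation). This call was lost without P5 replicate 2 or 3 or P28 replicate 1 or 3 (adjusted p = 0.0664 to 0.153), and the median of 0.21 turned to -0.06 with the covariate. Of 13 mitochondrially encoded genes 9 fell and 0 rose, or 11 and 0 adjusted over the list alone, with mt-Nd3 at -2.01 ± 0.54 (camera adjusted p = 0.000353, and adjusted p = 0.511 with an estimated correlation). Their median of -1.68 was -0.11 in the libraries under 6% and 0.13 with the covariate. None of 34 cytosolic ribosomal protein genes was called by limma over all genes or over the list alone, 0 passed an unadjusted p under 0.05, and edgeR and DESeq2 also called 0.

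In the signalling lists, 11 of 28 genes of the TGF-beta and BMP pathway rose and 2 fell between P5 and P28, or 11 and 4 adjusted over the list alone. Beside Grem1, the growth factor gene Gdf6 rose by 2.57 ± 0.40 and the activin antagonist Fst fell by 1.84 ± 0.47 (camera adjusted p = 0.0341, and adjusted p = 0.461 with an estimated correlation). That call was lost without P5 replicate 3 or P28 replicate 3 (adjusted p = 0.0559 to 0.114), in the libraries under 6% Gm26917 (adjusted p = 0.296) and with the covariate (adjusted p = 0.0768). Of 26 Wnt pathway genes 6 rose and 10 fell, or 8 and 11 adjusted over the list alone. Its antagonist genes changed in both directions, with Dkk1 at 4.61 ± 0.94, Dkk2 at -3.95 ± 0.74 and Sfrp1 at -3.54 ± 0.27. Of 16 genes of the IGF and growth hormone axis 4 rose and 5 fell, or 4 and 7 adjusted over the list alone, with the protease gene Pappa2 at -5.70 ± 0.83. The Hedgehog list had 2 of 11 genes that rose and 4 that fell, over all genes and over the list alone, with the antagonist Hhip at -1.81 ± 0.31. The list of YAP/TAZ targets and mechanosensors had 4 of 14 that rose and 2 that fell, also over the list alone, with Nt5e at 1.46 ± 0.20. Camera did not call the Wnt, IGF, Hedgehog and YAP/TAZ lists.

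Markers of other cell types also changed between P5 and P28. Of 9 osteoclast genes 7 rose and 0 fell, or 8 and 0 adjusted over the list alone, among them the fusion gene Ocstamp (4.50 ± 0.97). Of 12 osteoblast and osteocyte genes 7 rose and 0 fell, or 9 and 0 adjusted over the list alone, among them Bglap (4.87 ± 0.91) and Sost (4.77 ± 1.03). Of 11 neutrophil genes 6 rose and 0 fell, or 10 and 0 adjusted over the list alone, with Lcn2 at 3.66 ± 0.75. Of 7 B lineage genes 5 rose and 0 fell, or 7 and 0 adjusted over the list alone, with Pax5 at 2.45 ± 0.59. Camera adjusted p was 0.000216, 0.000605, 0.000788 and 0.00437 for these 4 lists, and for each the adjusted p was 0.461 with an estimated correlation. Of 11 nucleus pulposus and notochord genes 6 rose and 2 fell, or 7 and 2 adjusted over the list alone, with Lgals3 at 3.06 ± 0.39, the notochord gene T at 2.56 ± 0.55 and Krt8 at 2.44 ± 0.45 (camera adjusted p = 0.0334, and adjusted p = 0.655 with an estimated correlation). Without P5 replicate 2 or P28 replicate 2 this call was lost (adjusted p = 0.051 to 0.0729), as it was with the covariate (adjusted p = 0.888). Of 9 keratinocyte genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone, with Krt5 at -4.63 ± 1.25 and Sbsn and Dmkn as above (camera adjusted p = 0.0326, and adjusted p = 0.461 with an estimated correlation), a call lost without P5 replicate 3 or 4 (adjusted p = 0.0559 to 0.0574).

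Of 24 skeletal muscle genes Myh3 and Myh8 fell between P5 and P28, over all genes and over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.774 with an estimated correlation). Their levels at P5 ranged from 171.2 to 5367 and from 277.2 to 10060 between libraries. The camera call was lost without P5 replicate 3 or P28 replicate 2 or 3 (adjusted p = 0.104 to 0.136), and the median of -1.72 turned to 0.68 with the Gm26917 covariate and to 0.21 in the libraries under 6%. Of 12 pericyte and smooth muscle genes 2 fell and 0 rose, over all genes and over the list alone, with Mylk at -1.11 ± 0.26 (camera adjusted p = 0.0227, and adjusted p = 0.549 with an estimated correlation). This call was lost without P5 replicate 3 or P28 replicate 4 (adjusted p = 0.0529 to 0.0898), and the median of -0.75 turned to 0.51 under 6%. Camera did not call the macrophage list (3 rose and 1 fell of 12, or 4 and 2 adjusted over the list alone), with Cd68 at 1.81 ± 0.41 and Mrc1 at -1.76 ± 0.46. Nor did it call the Schwann cell list (1 rose and 3 fell of 10, also over the list alone), with Sox10 at -3.46 ± 0.77, or the adipocyte list (2 rose and 0 fell of 9, also over the list alone). Limma called none of 12 erythroid and 13 endothelial genes, over all genes or over each list alone. At an unadjusted p under 0.05, 0 and 3 of them passed, edgeR called 0 in both lists, and DESeq2 called 0 and 3.

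In all, limma called 4897 of 17577 genes between P5 and P28, of which 2641 rose and 2256 fell, and 1277 and 1370 of these differed at least 2-fold. An unadjusted p under 0.05 was reached by 7018 genes. Camera called 22 of the 39 lists, and 1 of them, the growth programme, with an estimated correlation. Of the 22, 15 kept the call under 6% Gm26917 and 14 with the log2 Gm26917 share as a covariate, as did 62 and 32 of the 115 called list members. The collagen processing, TGF-beta and BMP, oxidative phosphorylation, secretory, mitochondrially encoded, muscle and pericyte lists lost it in both settings (adjusted p = 0.217 to 0.851 and 0.057 to 0.759), and the nucleus pulposus list with the covariate alone (0.888). In the libraries under 6% Gm26917 the count was 1372 genes, 1119 of them shared with the 4897, and the P5 group there held 1 library, which was assumed to vary like the other groups. P28 had no library over 6%. With the covariate the count was 655, with 616 shared, and 4726 of the 4897 genes kept their sign. With each library rescaled to the same total, 32.8% of the called genes were higher against 53.9% with the deposited scaling, and the median of all genes shifted to -0.213.

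The comparison of P14 with P5 asked what changed over the first interval. The secreted protein gene Slurp1 (ENSMUSG00000022596, chromosome 15, 74724318 to 74728034) rose from 16.51 ± 9.963 to 373.6 ± 111.8 normalised reads (4.69 ± 0.50, adjusted p = 7.32e-05). Tnr rose from 10.61 ± 4.555 to 235.9 ± 74.61 (4.403 ± 0.35, adjusted p = 3.98e-06) and Grem1 from 663.6 ± 373.1 to 8969 ± 1307 (3.95 ± 0.39). Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), a matrix protein gene of young connective tissue, fell from 11530 ± 7717 to 495.4 ± 349.1 (-4.50 ± 0.64, adjusted p = 0.000679). Other genes with large increases were Fxyd3 (4.00 ± 0.47), Serpina1e (3.98 ± 0.74), Fam131c (3.58 ± 0.26), Lgi4 (3.30 ± 0.22), Foxo6os (3.17 ± 0.48), Plet1 (2.95 ± 0.49) and Cilp2 (2.88 ± 0.31). Large decreases were also measured in Myh8 (-6.81 ± 1.497), Myh3 (-6.68 ± 1.40), Col6a6 (-4.06 ± 0.52), Egfl6 (-4.04 ± 0.71), the mast cell genes Cpa3 (-3.96 ± 0.88), Cma1 (-3.73 ± 0.71) and Tpsb2 (-3.60 ± 0.67), Myom3 (-3.42 ± 0.79) and Adamts19 (-3.36 ± 0.59). Of these 20 genes, Slurp1, Tnr, Fxyd3, Fam131c and Lgi4 were also called in the libraries under 6% Gm26917, where P5 had 1 library.

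In the growth programme list 11 of 22 genes fell and 0 rose between P5 and P14, or 19 and 0 adjusted over the list alone (camera adjusted p = 1.37e-11, and adjusted p = 0.0618 with an estimated correlation). Dlk1 fell by 3.30 ± 0.35, Mest by 2.58 ± 0.42 and Igf2 by 1.46 ± 0.33 (adjusted p = 0.0111). H19 fell by 1.74 ± 0.47 (adjusted p = 0.0305), a call lost without P5 replicate 1, 2 or 3 or P14 replicate 2, 3 or 4 (adjusted p = 0.0531 to 0.108). Of 26 glycolysis and hypoxia genes 15 rose and 0 fell, or 22 and 0 adjusted over the list alone, with Egln3 at 1.44 ± 0.31 and the glucose transporter gene Slc2a1 at 1.40 ± 0.31 (camera adjusted p = 2.25e-12, and adjusted p = 0.272 with an estimated correlation). Of 18 clock genes 7 rose and 0 fell, or 9 and 0 adjusted over the list alone, with Nr1d1 at 1.51 ± 0.24 and Dbp at 1.31 ± 0.29 (camera adjusted p = 1.92e-05, and adjusted p = 0.397 with an estimated correlation). The immediate-early list had 3 of 20 genes that rose, or 8 adjusted over the list alone (camera adjusted p = 0.00265, and adjusted p = 0.538 with an estimated correlation), with Klf4 at 1.00 ± 0.21. In the S phase list 3 of 28 genes fell and 0 rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 9.5e-06, and adjusted p = 0.538 with an estimated correlation), with Tyms at -0.99 ± 0.19. Of 27 G2/M genes limma called 0 over all genes and over the list alone, with 15 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2 (camera adjusted p = 2.28e-07, and adjusted p = 0.54 with an estimated correlation). Mki67 differed by -0.84 ± 0.38 (adjusted p = 0.193).

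Elastic fibre genes fell in 6 of 17 cases between P5 and P14 with 0 that rose, or 8 and 0 adjusted over the list alone, with Mfap4 at -2.39 ± 0.42 and Fbn2 at -1.99 ± 0.21 (camera adjusted p = 7.62e-05, and adjusted p = 0.238 with an estimated correlation). Of 14 hypertrophy and mineralisation genes 5 rose and 0 fell, or 7 and 0 adjusted over the list alone, with Ibsp at 2.84 ± 0.65 and the phosphatase gene Alpl at 2.39 ± 0.54 (camera adjusted p = 6.52e-05, and adjusted p = 0.516 with an estimated correlation). Of 29 collagen processing genes 9 rose and 2 fell, or 14 and 3 adjusted over the list alone, with Pcolce2 at 2.24 ± 0.34 and Loxl2 at 1.36 ± 0.31 (camera adjusted p = 0.00051, and adjusted p = 0.54 with an estimated correlation). Lox, the gene of the main collagen crosslinking oxidase, rose by 1.22 ± 0.36 (adjusted p = 0.0439). That call was lost without any 1 of P5 replicates 1, 2 and 3, P14 replicates 1, 2 and 4, P21 replicates 3 and 4 and P28 replicates 2, 3 and 4 (adjusted p = 0.0502 to 0.143). Scx rose by 2.84 ± 0.62 (adjusted p = 0.00981) and Bop1 by 4.08 ± 0.86, with the low values of both in P5 replicates 1 to 3 given above, and the Scx difference was -0.03 under 6% Gm26917. The call was also lost without the pools of mostly 1 sex (adjusted p = 0.0804), with edgeR (adjusted p = 0.108) and with DESeq2 (adjusted p = 0.0554). The camera calls of the cartilage-type matrix (adjusted p = 0.0255), chondrogenic regulator (adjusted p = 0.00926) and secretory lists (adjusted p = 0.000291) went to adjusted p = 0.556, 0.538 and 0.551 with an estimated correlation. Of 18 cartilage-type genes 3 rose and 2 fell, or 5 and 2 adjusted over the list alone. Of 27 secretory genes 1 rose, or 0 adjusted over the list alone, and of 13 chondrogenic regulators limma called 0 both ways, with 5 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2. The cartilage-type call was lost without P5 replicate 1, 2 or 3 or P14 replicate 1 (adjusted p = 0.0544 to 0.156) and the chondrogenic call without P5 replicate 3 (adjusted p = 0.0719). In the libraries under 6%, the medians of the collagen processing, cartilage-type, chondrogenic and secretory lists turned from 0.51, 0.50, 0.40 and 0.40 to -0.06, -0.29, -0.05 and -0.05.

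Vascular markers were lower at P14 than at P5. Of 13 endothelial genes 7 fell and 0 rose, or 11 and 0 adjusted over the list alone, with Esam at -1.99 ± 0.43 and Egfl7 at -1.82 ± 0.34 (camera adjusted p = 4.9e-08, and adjusted p = 0.431 with an estimated correlation). Of 12 pericyte and smooth muscle genes 4 fell and 0 rose, or 6 and 0 adjusted over the list alone, with Notch3 at -2.15 ± 0.41 (camera adjusted p = 0.000136, and adjusted p = 0.516 with an estimated correlation). Of 12 macrophage genes 3 fell and 0 rose, or 6 and 0 adjusted over the list alone, with Mrc1 at -2.06 ± 0.46 (camera adjusted p = 0.00573, and adjusted p = 0.55 with an estimated correlation). Within the libraries over 6% Gm26917 (3 at P5 and 2 at P14) these 3 lists were called in the same direction. Under 6% (1 at P5 and 2 at P14) their medians of -1.48, -1.02 and -1.03 turned to 0.05, 0.09 and 0.35. Of 7 B lineage genes 6 rose and 0 fell, or 7 and 0 adjusted over the list alone, with Pax5 at 2.84 ± 0.59 (camera adjusted p = 4.59e-06, and adjusted p = 0.272 with an estimated correlation). Of 11 nucleus pulposus genes 5 rose and 0 fell, or 5 and 1 adjusted over the list alone, with Krt8 at 2.69 ± 0.45 (camera adjusted p = 0.00416, and adjusted p = 0.54 with an estimated correlation). Camera also called the neutrophil, erythroid and skeletal muscle lists (medians 1.62, 1.44 and -2.68, adjusted p = 0.00109, 0.00299 and 4.87e-06, and adjusted p = 0.54, 0.55 and 0.54 with an estimated correlation). Myh3 and Myh8 fell, or 7 muscle genes adjusted over the list alone. Limma called 0 neutrophil and 0 erythroid genes, or 4, all higher, and 0 adjusted over each list alone, with 5 in each list at an unadjusted p under 0.05, 0 by edgeR in both, and 3 and 0 by DESeq2. The keratinocyte list (2 of 9 genes rose and 0 fell, or 4 and 1 adjusted over the list alone, camera adjusted p = 0.041, and adjusted p = 0.272 with an estimated correlation) lost its call without P5 replicate 3, P5 replicate 4, P14 replicate 2 or P21 replicate 1 (adjusted p = 0.0508 to 0.111).

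Between P5 and P14 limma called 1553 genes, of which 857 rose and 696 fell, 470 and 461 of them at least 2-fold, and 4129 reached an unadjusted p under 0.05. Camera called 21 of 39 lists, and 0 with an estimated correlation. Of the 21, 14 kept the call under 6% Gm26917 and 18 with the covariate, as did 3 and 58 of the 84 called list members. The cartilage-type, chondrogenic and secretory lists lost it in both settings (adjusted p = 0.132 to 0.839 and 0.0528 to 0.238), and the collagen processing, macrophage, endothelial and pericyte lists under 6% alone (0.417 to 0.914). Within the libraries over 6% Gm26917 limma called 1936 genes, 1091 of them shared with the 1553. Within those under 6% it called 35, with 28 shared, and 1529 of the 1553 kept their sign. With the covariate it called 891, with 855 shared. The count moved by more than 1.5 times without P5 replicate 1 (946), P5 replicate 2 (950), P5 replicate 3 (913), P5 replicate 4 (2517) or P14 replicate 2 (892). Rescaled to the same total, 23.5% of called genes were higher against 55.2%, and the median of all genes shifted to -0.242.

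The comparison of P21 with P14 asked what changed over the second interval, in which weaning falls in mice. Genes induced by interferon were higher at P21. Gbp4 (ENSMUSG00000079363, chromosome 5, 105115767 to 105139586), an interferon-induced GTPase gene, rose from 14.25 ± 4.862 to 271.6 ± 71.91 normalised reads (4.18 ± 0.53, adjusted p = 0.00209). Iigp1, of the same broad group of GTPases, rose by 3.94 ± 0.60 and Nlrc5, a regulator of antigen presentation genes, by 3.38 ± 0.52. Of 22 interferon response genes 7 rose and 0 fell, or 21 and 0 adjusted over the list alone, with Gbp3 at 3.24 ± 0.50, Ifit3b at 2.71 ± 0.57 and Xaf1 at 2.25 ± 0.46 (camera adjusted p = 1.15e-19, and adjusted p = 0.136 with an estimated correlation). The other genes with the largest increases were Tgtp2 (4.04 ± 0.73), Chodl (3.64 ± 0.80), Wfikkn2 (3.50 ± 0.58), Chil3 (3.42 ± 0.71), Inmt (3.34 ± 0.66), Gbp2 (3.23 ± 0.61) and Gbp7 (2.71 ± 0.49). The largest decreases were in A2m (-3.23 ± 0.74), the small cytoplasmic Y RNAs Rny3 (-2.998 ± 0.28) and Rny1 (-2.52 ± 0.26), Dlk1 (-1.89 ± 0.35), Cthrc1 (-1.88 ± 0.36), Tnc (-1.87 ± 0.32), Cdkn1c (-1.83 ± 0.34), Foxa3 (-1.78 ± 0.40), Mest (-1.77 ± 0.42) and Capn6 (-1.75 ± 0.26). Igf2 fell by 1.496 ± 0.33 (adjusted p = 0.0351). Of these 21 genes, Gbp4, Iigp1, Nlrc5, Rny3, Rny1 and Capn6 kept their call whichever library was left out. The other 15 lost it in 2 to 12 of the 16 cases. The calls lost numbered 15 without P21 replicate 3 or 4 (adjusted p = 0.0578 to 0.175), 14 without P14 replicate 4 (0.0579 to 0.128), 9 without P14 replicate 3 (0.0527 to 0.094) and 8 without P14 replicate 1 (0.0517 to 0.121). They numbered 4 without P5 replicate 1 or 2, 3 without P14 replicate 2, P28 replicate 1 or P28 replicate 4, 2 without P28 replicate 2, and 1 without P21 replicate 1 or 2 (0.0505 to 0.0661). In the libraries under 6% Gm26917 Rny3 and Rny1 were called and the other 19 were not. Among the list members, Gbp3 was lost without P21 replicate 4 (adjusted p = 0.0573), Ifit3b without P14 replicates 1, 3 or 4 or P21 replicates 1, 3 or 4 (0.0569 to 0.129) and Xaf1 without P14 replicates 1, 3 or 4 or P21 replicates 3 or 4 (0.0515 to 0.102).

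Of 22 growth programme genes 5 fell and 0 rose between P14 and P21, or 13 and 0 adjusted over the list alone (camera adjusted p = 8.79e-10, and adjusted p = 0.113 with an estimated correlation). H19 differed by -1.95 ± 0.47 (adjusted p = 0.0538). Of 11 fibril-associated and type VI collagens 3 fell and 0 rose, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.000829, and adjusted p = 0.136 with an estimated correlation). Its members Col14a1 (-1.49 ± 0.31) and Col12a1 (-1.24 ± 0.25) lost their calls without P14 replicate 4 or P21 replicate 3 or 4, Col14a1 also without P14 replicate 3 or P21 replicate 1, and Col12a1 also without P14 replicate 1 (adjusted p = 0.0573 to 0.11). Fbn2 (-1.41 ± 0.21) and Sbsn (1.99 ± 0.25) kept theirs in every such case. Of 29 collagen processing genes 1 fell and 0 rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 9.46e-06, and adjusted p = 0.62 with an estimated correlation), and of 26 Wnt genes 1 fell and 0 rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.00149, and adjusted p = 0.136 with an estimated correlation). Of 13 endothelial genes limma called 0 over all genes and 8, all higher, over the list alone, with 9 at an unadjusted p under 0.05, 0 by edgeR and 5 by DESeq2 (median 1.05, camera adjusted p = 2.16e-07, and adjusted p = 0.579 with an estimated correlation). The neutrophil list had 1 gene of 11 that rose, or 4 adjusted over the list alone (camera adjusted p = 3.3e-05, and adjusted p = 0.62 with an estimated correlation). Of 13 mitochondrially encoded genes limma called 0, also over the list alone, with 0 at an unadjusted p under 0.05 and 0 by edgeR and DESeq2. Camera called that list (median -0.91, adjusted p = 0.00069, and adjusted p = 0.62 with an estimated correlation), and the median turned to 0.13 under 6% Gm26917. Col1a1, Col1a2, Col2a1, Acan, Eln, Lox, Scx, Mkx, Tnmd, Sox9, Mki67, Top2a, Tgfb1 and Gli1 were not called, with Lox at -1.07 ± 0.36 (adjusted p = 0.149) and Scx at -1.57 ± 0.62 (adjusted p = 0.228), beside Bop1 at -1.53 ± 0.86.

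Camera called 9 more lists between P14 and P21 whose call depended on 1 library. These were the fibrillar collagens (median -0.27, adjusted p = 0.0468), chondrogenic regulators (-0.14, 0.0413), hypertrophy genes (-0.60, 0.0216), secretory genes (-0.27, 0.0216), clock genes (0.14, 0.0413), nucleus pulposus genes (0.95, 0.00341), B lineage genes (1.14, 0.00745), macrophage genes (0.69, 0.00164) and keratinocyte genes (0.59, 0.0266). With an estimated correlation the adjusted p was 0.759 for the secretory genes, 0.152 for the keratinocyte genes and 0.62 for the other 7. Members were called in the chondrogenic (2 fell, also over the list alone), clock (2 rose, or 5 rose and 1 fell over the list alone) and keratinocyte lists (2 rose, or 3 over the list alone). In the other 6 lists limma and edgeR called 0, with 2 fibrillar, 4 hypertrophy, 4 secretory, 3 nucleus pulposus, 2 B lineage and 2 macrophage genes at an unadjusted p under 0.05, and DESeq2 called 2 hypertrophy and 2 macrophage genes and 0 in the other 4. Adjusted over the list alone, 3 hypertrophy genes fell, 2 macrophage genes rose and 0 were called in the other 4 lists. The calls of the nucleus pulposus, B lineage, macrophage and keratinocyte lists were lost without P21 replicate 1 (adjusted p = 0.0687 to 0.113), and that of the nucleus pulposus list also without P14 replicate 3, and that of the keratinocyte list also without P21 replicate 2 (0.0556). The hypertrophy and secretory lists lost theirs without P14 replicate 1, P14 replicate 2 or P21 replicate 2 (0.0997 to 0.447). The chondrogenic list lost its call without P14 replicates 2, 3 or 4 or P21 replicates 1 or 2 (0.0518 to 0.156), and its median turned to 0.01 without P21 replicate 1 and to 0.11 when libraries were rescaled to the same total. The fibrillar collagen list lost its call without P14 replicate 2, any P21 library or P28 replicates 1 or 4 (0.0509 to 0.19), and the clock list without P5 replicates 3 or 4, P14 replicates 1 or 2, P21 replicates 2, 3 or 4 or P28 replicate 4 (0.0519 to 0.214). The Schwann cell list, which was not called, had a median of -0.06 and a mean of -0.01 with an upward camera direction.

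Between P14 and P21 limma called 241 genes, of which 122 rose and 119 fell, 88 and 63 of them at least 2-fold, and 2707 reached an unadjusted p under 0.05. Camera called 17 of 39 lists, and 0 with an estimated correlation. Of the 17, 13 kept the call under 6% Gm26917, 14 with the covariate and 8 in all of the settings added later. Of the 21 called list members 0 kept it under 6%, 6 with the covariate and 2 whichever library was left out. Under 6% the chondrogenic (adjusted p = 0.0709), mitochondrially encoded (0.278), nucleus pulposus (0.633) and B lineage lists (0.0608) lost it, and with the covariate the clock (0.109), mitochondrially encoded (0.538) and nucleus pulposus lists (0.308). Within the libraries under 6% Gm26917 (2 at P14 and 4 at P21) limma called 7 genes, all 7 among the 241, and P21 had no library over 6%. With the covariate it called 82, with 60 shared. Without P14 replicate 2 and P21 replicates 1 and 2, which carried the neuronal transcripts, it called 704, with 195 shared. P21 was then replicates 3 and 4 alone, which may not be separate pools. With P21 replicates 3 and 4 averaged as 1 sample limma called 13, and without the 3 pools of mostly 1 sex it called 4. The count depended on single libraries: it was 12 without P21 replicate 4, 17 without P21 replicate 3, 28 without P14 replicate 4, 73 without P14 replicate 3, 102 without P14 replicate 1, 144 without P5 replicate 2, 428 without P5 replicate 4 and 758 without P21 replicate 2. Rescaled to the same total, 519 genes were called and 90.2% of them were higher, against 50.6%, with the median of all genes shifted to 0.223.

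The comparison of P28 with P21 asked what changed over the last interval. Dlk1 fell further, from 139.9 ± 37.83 to 17.98 ± 10.56 normalised reads (-3.04 ± 0.35, adjusted p = 0.00118). Hhip (ENSMUSG00000064325, chromosome 8, 79965851 to 80058006), which encodes a Hedgehog-binding antagonist, fell from 2238 ± 723.7 to 373.3 ± 138.5 (-2.61 ± 0.31, adjusted p = 0.00137). The Y RNAs Rny3 (ENSMUSG00000064945, chromosome 6, 47781624 to 47781725) and Rny1 (ENSMUSG00000065701, chromosome 6, 47788069 to 47788180) rose from 209.1 ± 77.74 to 1137 ± 173.2 (2.503 ± 0.28) and from 153.7 ± 39.65 to 825.8 ± 120.5 (2.44 ± 0.26). Sod3, the extracellular superoxide dismutase gene, rose from 1078 ± 278.2 to 3337 ± 587.9 (1.65 ± 0.23, adjusted p = 0.00609), and P4ha3 fell by 1.60 ± 0.22. Also higher were Slc36a2 (3.78 ± 0.62), Col22a1 (3.38 ± 0.66), Phex (3.10 ± 0.59), Cthrc1 (1.98 ± 0.36), Tnc (1.70 ± 0.32), Etv4 (1.70 ± 0.32) and Olfml3 (1.59 ± 0.31). Also lower were Erc2 (-2.44 ± 0.47), Zim1 (-2.06 ± 0.38), Fstl4 (-1.54 ± 0.23), Rasgef1b (-1.44 ± 0.26), Peg3 (-1.41 ± 0.27), Ntn1 (-1.37 ± 0.21) and Ablim1 (-0.87 ± 0.16). The calls of Dlk1, Hhip, Rny3, Rny1, Sod3 and P4ha3 remained whichever library was left out, and the other 14 were lost in 1 to 12 of the 16 cases. The calls lost numbered 14 without P21 replicate 4, 13 without P21 replicate 3, P28 replicate 1 or P28 replicate 3, 11 without P5 replicate 1, P5 replicate 2, P14 replicate 4 or P28 replicate 2, 9 without P21 replicate 2, 5 without P14 replicate 1, 3 without P14 replicate 2, 2 without P28 replicate 4 and 1 without P21 replicate 1 (adjusted p = 0.0506 to 0.15). Tnc was not called in the libraries under 6% Gm26917 (adjusted p = 0.0573).

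Skeletal cell markers were higher at P28 than at P21. Of 9 osteoclast genes limma called 0 over all genes and 8, all higher, over the list alone, with 8 at an unadjusted p under 0.05, 0 by edgeR and 5 by DESeq2 (median 2.68, camera adjusted p = 5e-09, and adjusted p = 0.258 with an estimated correlation). Of 12 osteoblast and osteocyte genes Phex rose, and 9 rose adjusted over the list alone (median 2.04, camera adjusted p = 5e-09, and adjusted p = 0.337 with an estimated correlation). The score of the osteoclast list was higher in P21 replicate 1 than in the other P21 libraries (8.38 against 6.28 to 6.37). Of 22 growth programme genes Dlk1, Peg3 and Plagl1 fell and 0 rose, or 7 and 0 adjusted over the list alone (camera adjusted p = 4.84e-08, and adjusted p = 0.233 with an estimated correlation). The call of Plagl1 (-0.86 ± 0.17) was lost without P5 replicates 1 or 2, P14 replicates 1 or 4, any P21 library or P28 replicates 1, 2 or 3 (adjusted p = 0.0514 to 0.147). Of 29 collagen processing genes Bmp1 rose and P4ha3 fell, or 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.53e-06, and adjusted p = 0.56 with an estimated correlation). Bmp1 (0.74 ± 0.12) was lost without P21 replicates 3 or 4 or P28 replicates 1, 2 or 3 (adjusted p = 0.0503 to 0.104). The matrix protease list (median 0.47, camera adjusted p = 0.000249, and adjusted p = 0.337 with an estimated correlation) and the hypertrophy list (0.75, adjusted p = 1.22e-05, and adjusted p = 0.515 with an estimated correlation) had 0 genes called by limma. Adjusted over each list alone, 7 rose and 2 fell in the former and 3 rose in the latter, with 11 and 7 genes at an unadjusted p under 0.05, 0 by edgeR in both, and 3 in each by DESeq2.

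Camera called 2 further lists as higher at P28 than at P21 and 2 as lower whichever library was left out. The oxidative phosphorylation genes (median 0.28, adjusted p = 4.53e-06) and the secretory genes (0.31, adjusted p = 0.000148) were higher, and the interferon response genes (-0.63, adjusted p = 0.000223) and B lineage genes (-1.56, adjusted p = 1.46e-05) were lower. With an estimated correlation the adjusted p was 0.679 for the first 3 of these and 0.337 for the B lineage list. Limma called 0 members of these 4 lists and edgeR 0, with 5, 2, 3 and 6 at an unadjusted p under 0.05 and 0, 0, 0 and 1 by DESeq2, and over the list alone 4 B lineage genes fell and 0 genes of the other 3 lists were called. The calls of the G2/M list (median -0.46, adjusted p = 0.000223) and the nucleus pulposus list (-0.82, adjusted p = 0.00255) were lost without P21 replicate 1 (adjusted p = 0.644 and 0.174). Those of the neutrophil list (-0.73, adjusted p = 0.00857), skeletal muscle list (1.45, adjusted p = 0.00877) and TGF-beta and BMP list (0.21, adjusted p = 0.0181) were also lost in this way. The libraries were P21 replicate 1 or P28 replicate 3 for the neutrophil list (adjusted p = 0.0765 to 0.478), P21 replicate 1 or P28 replicates 1 or 4 for the muscle list (0.0913 to 0.847), and P21 replicate 2 or P28 replicate 3 for the TGF-beta list (0.105 to 0.245). With an estimated correlation the adjusted p was 0.753 for G2/M, 0.797 for muscle, 0.56 for TGF-beta and BMP, and 0.679 for the neutrophil and nucleus pulposus lists. Limma and edgeR called 0 members of these 5 lists, with 0 G2/M, 4 nucleus pulposus, 2 neutrophil, 1 muscle and 7 TGF-beta genes at an unadjusted p under 0.05, and 0, 2, 2, 2 and 3 by DESeq2. Adjusted over the list alone, 2 neutrophil genes fell and 3 TGF-beta genes rose, with 0 called in the other 3 lists. The median, mean and camera direction differed in sign for the cartilage-type (0.12, -0.10, up), Hedgehog (0.02, -0.21, down), Wnt (-0.10, 0.09, up), IGF (-0.06, 0.05, up) and keratinocyte lists (0.19, -0.15, up), none of which was called. Col1a1, Col1a2, Col2a1, Acan, Eln, Lox, Scx, Mkx, Tnmd, Sox9, Mki67, Top2a, Igf2, H19, Tgfb1 and Gli1 were not called, with Igf2 at -1.12 ± 0.33 (adjusted p = 0.15), Tgfb1 at 0.73 ± 0.17 (adjusted p = 0.0703) and Scx at 0.86 ± 0.62 beside Bop1 at 0.46 ± 0.86.

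Between P21 and P28 limma called 38 genes, of which 21 rose and 17 fell, 16 and 15 of them at least 2-fold, and 2096 reached an unadjusted p under 0.05. Camera called 15 of 39 lists, and 0 with an estimated correlation. All 8 libraries of these ages had a Gm26917 share under 6%, and with the 3 under-6% libraries of the younger ages 129 genes were called, 34 of them shared. With the covariate 106 were called, including all 38. With P21 replicates 3 and 4 averaged as 1 sample 6 were called, and without the 3 pools of mostly 1 sex 87. Without P14 replicate 2 and P21 replicates 1 and 2, 36 were called, with 11 shared. P21 was then replicates 3 and 4 alone, perhaps 1 pool. Of the 20 genes named above, Dlk1, Hhip, Rny3, Rny1 and P4ha3 kept their call in all of the settings added later and the other 15 did not. The count was 6 without P21 replicate 4, 7 without P28 replicate 1 or 3, 11 without P28 replicate 2, 13 without P21 replicate 3, 16 without P5 replicate 1, 17 without P5 replicate 2 and 20 without P14 replicate 4. It was 99 without P21 replicate 1, 101 without P14 replicate 3, 108 without P5 replicate 4 and 113 without P5 replicate 3. Rescaled to the same total, 18 genes were called and 22.2% of them were higher, against 55.3%, with the median of all genes shifted to -0.173. DESeq2 called 668 genes, 40.4% of them higher.

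The test over all 4 ages asked which genes differed among any of them. Limma's F test called 4449 of 17577 genes, 1208 in the 11 libraries under 6% Gm26917 and 1163 with the covariate. Tnr, Grem1, Dlk1, Igf2 and H19 had their extreme age means at P5 and P28. The Y RNA genes Rny1 and Rny3 had their lowest age mean at P21, where each of the 4 libraries lay below each of the 12 others: 123.1 to 208.9 against 304.1 to 1292 for Rny1, and 127.7 to 294.4 against 651.2 to 2655 for Rny3. Rny1 and Rny3 have 112 and 102 bases, under the 150 of a read, and an effect of library preparation was not tested. The first principal component of the log2 values took 34.9% of the variance and the next 3 took 15.1%, 11.1% and 10.5%.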

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

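The tests chosen after the results were seen are those of age and of brain sources for the nervous system transcripts, of an added genomic copy at Scx, and of exchanged samples; the others were chosen before.

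In 82 measures, 328 groups of 4 libraries were examined for a library far from the other 3 of its age, by the gap to its nearest neighbour as a share of the range of the group. There were 32 such cases, in 9 libraries, where chance gives about 1 in 20 groups. P21 replicate 1 had 11 of them. It was high for Acan (0.836), Mki67 (0.833), the matrix protease (0.85), hypertrophy (0.924), S phase (0.964), osteoclast (0.955) and adipocyte lists (0.867), and low for Col1a2 (0.856), its share of reads (0.851), Xist (0.962) and the clock list (0.892). P5 replicate 4 had 8. It was high for Col2a1 (0.873), Lox (0.879), Scx (0.877), Bop1 (0.907) and the cartilage-type (0.83) and collagen processing lists (0.849), and low for the IGF (0.967) and Schwann cell lists (0.889). P28 replicate 3 was high for Col1a1 (0.92), Col1a2 (0.887) and the share of reads of Col1a2 (0.874), and low for the Schwann cell list (0.946). P14 replicate 1 was low for Tnc (0.892), the elastic fibre list (0.899) and the tendon-type list (0.848). P21 replicate 2 was low for the small leucine-rich proteoglycans (0.961) and the interferon list (0.841). Single cases were Xist low in P5 replicate 3 (0.839), Cma1 low in P21 replicate 3 (0.88), the Hedgehog list high in P28 replicate 2 (0.832) and Tnc low in P28 replicate 4 (0.917).

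Central nervous system transcripts were high in P14 replicate 2 and P21 replicates 1 and 2, with a median log2 ratio of 4.64 over the other libraries of these ages for 22 genes and a lowest of 1.26. The abundant astrocyte gene Slc1a2 had 802.7, 2179 and 1968 there and 1.97 to 108.3 elsewhere. Age is argued against as the cause, since P21 replicates 1 and 2 exceeded P21 replicates 3 and 4 by a median of 4.27, and peripheral nerve is argued against by its 9 genes, with a median of -0.03. The ratio of the excess in P21 replicate 1 to that in P21 replicate 2 had an SD of 0.37 over 20 genes, which is consistent with brain tissue RNA or reads from one source in these 2 libraries. For P14 replicate 2 over P21 replicate 2 the SD was 0.59, wider than predicted for one source and narrower than predicted for different ones, so a common source with P14 replicate 2 stays open. Whether the RNA or reads entered at dissection, library preparation or sequencing stays open.

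Scx was 3.56 higher on the log2 scale in P5 replicate 4 than in P5 replicates 1 to 3. The 10 other annulus and tendon markers had a median ratio of 0.23 (-1.99 to 1.11). This argues against dilution by tissue that lacks these markers, and cannot show tissue that has them. List scores in P5 replicates 1 to 3 exceeded P5 replicate 4 for muscle (7.40 to 10.21 against 5.88), endothelial (7.73 to 8.51 against 6.62) and macrophage genes (6.38 to 6.86 against 4.79). The nucleus pulposus score was lower, and the osteoclast and osteoblast scores lay on both sides. More tissue of other kinds in these pools stays open. Bop1 differed by 5.04, more than Scx, and the genes share 0 exonic bases, but reads from the Bop1 intron around Scx cannot be told apart from Scx reads while the strand setting is unknown. The Bop1 excess over the Scx excess had a median of 2.49, more than Scx reads counted for Bop1 would add, and a log2 SD of 0.31 over the 13 libraries with an excess, while Mroh1 and Hsf1 differed by -0.68 and -0.31, so an added genomic copy of the region of Scx and part of Bop1, such as a reporter transgene, may be present in most pools, although the labels give wild-type. Fabp2, a gene of chromosome 3 chosen after its values were seen, followed the same split at the low counts given above. Neither shared reads nor a copy of this region alone would give this. Age as a cause of the Scx increase stays open and untested, and Scx fold changes involving P5 follow this library split.

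Between P14 and P21, 2 of the 35 splits of the 8 libraries gave as many genes as the real one (241), the highest other giving 595, so chance cannot be excluded for this count. That split exchanges P14 replicate 2 with P21 replicate 2. On a scale from P5 to P28 over 4897 genes, P14 replicate 2 lay at 0.73 and P21 replicate 2 at 0.56, against 0.47 to 0.52 in the other P14 and 0.84 to 0.92 in the other P21 libraries, which goes with exchanged samples. The growth programme score, which was lower at each later age, argues against it, since it was higher in P14 replicate 2 than in P21 replicate 2 by 0.63 (pooled SD 0.28). Unequal ages or tissue mixtures within these pools stay open.

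Chance is argued against for P14 against P5 (1553, highest other 1124) and P28 against P5 (4897, highest other 3). In each, 1 of only 35 splits, the real one, gave as many genes. The same holds for the 4 ages (1 of 100 splits, 4449, highest other 519). For P28 against P21 the real split of 35 also stood alone (38, highest other 7). That argues against chance only if P21 replicates 3 and 4 are separate pools, since averaging them left 6 genes. The P14 against P5 split with 1124 genes exchanges P5 replicate 4 with P14 replicate 3. It sets the 4 libraries with the highest Gm26917 shares (8.49% to 12.1%) against 4 others, of which P14 replicate 4 had 8.05%. The 1553 may partly follow that share.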

How the results depend on the processing

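The settings on Gm26917, nervous system transcripts, P21 replicates 3 and 4 and one-sex pools, and their tests, were chosen after the results were seen.

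Under the settings chosen in advance, of the comparisons of named genes with each setting 3675 kept direction and side of the threshold, 293 lost the call and 48 gained one. For list members these numbers were 9171, 531 and 20. For lists they were 4098, 183 and 74, with 1 reversal of the direction of the test, and 74 of 156 list tests lost the call with an estimated correlation. The reversal was the ribosomal list at P28 against P5 (-0.15, quantile normalization). The median of the chondrogenic list at P21 against P14 also changed sign in the settings given above. There the test kept its direction and lost its call. Counts stayed within 1.5 times in 106 cases. Those that did not, leaving single libraries aside, were P28 against P21 with pseudocount 10 (90), the same total (18), 8 samples (82), edgeR (24) and DESeq2 (668), and P21 against P14 with the same total (519), 8 samples (102) and DESeq2 (832). Without single libraries, counts ranged from 892 to 2517 (P14 against P5), 12 to 758 (P21 against P14), 6 to 113 (P28 against P21), 3590 to 5493 (P28 against P5) and 3105 to 5323 (genes changed over the 4 ages). With a replicate block they were 1506, 181, 32, 4882 and 4322. Replicate numbers did not pair the libraries: the mean correlation was 0.042 for equal and -0.014 for different numbers. The cause was not tested.

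With the Gm26917 covariate counts were 891, 82, 106, 655 and 1163 in that order, and under 6% they were 35, 7, 129, 1372 and 1208, with fewer samples. Without the nervous system libraries P21 against P14 had 704 (P21 replicates 3 and 4 alone). With P21 replicates 3 and 4 averaged the P21 comparisons had 13 and 6. Without the one-sex pools counts were 1012, 4 and 87 for the 3 steps. Reversed at P28 against P5 with the covariate were mt-Nd5 (0.12), mt-Nd2 (0.057), Pmp22 (-0.14) and the collagen processing (-0.038), oxidative phosphorylation (-0.06), secretory (-0.20), ribosomal (-0.36), mitochondrial (0.13) and muscle lists (0.68). Reversed under 6% were, at P14 against P5, Scx (-0.026), Mcam (0.23) and the cartilage-type (-0.29), collagen processing (-0.061), chondrogenic (-0.048), secretory (-0.052), macrophage (0.35), adipocyte (1.09), endothelial (0.054) and pericyte lists (0.089). At P28 against P5 they were Acan (-0.13), Scx (-0.54), Col5a3 (0.41) and the cartilage-type (-1.06), collagen processing (-0.15), secretory (-0.12), endothelial (0.83) and pericyte lists (0.51), and the median of the muscle list changed sign (0.21) without a change in the direction of the test. At P21 against P14 the mitochondrial (0.13) and muscle lists (1.22) reversed under 6% and without the one-sex pools, settings that both drop P14 replicates 3 and 4. The cause was not tested.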

Other observations

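The mast cell, cornified-type, imprinted and other added lists were made after genes of these kinds had been seen to change, so no p is given for them on the same comparison except for imprinted genes outside the growth list, whose test was chosen before its result was seen, and its repeat without named genes, chosen after.

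Of 7 mast cell genes 5 fell between P5 and P28 and 0 rose (median -5.56), with Tpsb2 from 154.8 ± 74.14 to 1.067 normalised reads. Hdc and Gata2, at 0.27 and -0.58, were not called. Of 12 genes typical of cornified epithelia, which include keratin, cell junction and regulator genes, 7 rose and 1 fell (median 3.23), with Slurp2 at 4.93 ± 0.57 beside Slurp1, Sbsn and Dmkn, while the keratin gene Krt5 fell by 4.63 ± 1.25.

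The remaining added lists gave these values at P28 against P5. Of 20 bone marrow genes 8 rose and 0 fell (median 1.71), and of 7 osteoclast-restricted genes 6 rose and 0 fell (median 3.94). Of 22 central nervous system genes 1 fell and 0 rose (median -0.30). Of 10 peripheral nerve genes 1 rose and 3 fell (-0.98), and of 10 annulus and tendon markers other than Scx 4 rose and 2 fell (0.82).

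Of 30 imprinted genes 25 fell and 1 rose between P5 and P28 (median -2.36), and 12 of them are in the growth programme list. Of the 18 others 13 fell, 4 were not called and Impact rose by 0.49 ± 0.14. The median of the 18 was -2.07, with Nespas at -5.05 ± 0.50, Rtl1 at -3.19 ± 0.41 and Zdbf2 at -2.55 ± 0.20. Camera gave p = 8.51e-05 for these 18 genes with limma and an estimated correlation of 0.0193, over 16 libraries (n = 16). Magel2 and Zim1 among them had already been named for their decreases. Without them, 16 genes had a median of -1.93 and p = 7.04e-05 (limma, n = 16). This goes with the hypothesis that imprinted genes fell as a class in this tissue, which was formed on the same libraries. Zim1 (chromosome 7, 6671269 to 6696450) lies beside Peg3 (6703892 to 6730431) of the growth list. Whether others of the 18 are neighbours of growth list genes was not tested. Both p may therefore depend on decreases that had already been seen. A change in the mix of cell types stays open as a cause.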
